A study of Rattus norvegicus with 6 samples.

How the data were processed

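Total RNA from the renal cortex of 6 male Sprague-Dawley rats, 3 given corn oil and 3 given ADBAQ, was extracted with a column kit, checked on a Bioanalyzer, amplified from a small input and labelled with Cy3, per the labels' protocols. Each sample was hybridised alone to an Agilent rat array of 62976 spots. Per the file headers, spots were read with Agilent Feature Extraction 10.7.1.1 (10.7 in the submitters' processing notes), which subtracted the background. The deposited values used here are the processed signal intensity of each spot on a linear scale, with the median signal and median background intensity for an alternative, and the flags per spot (other units) for control, outlier, saturated and well above background, per the file headers. The authors' table of the whole series, also deposited, was compared with the scanner values: each column was the processed signal as a ratio to 1 constant per array, on a linear scale, not log transformed and not centred. That constant lay within 0.0857% of the array's 75th percentile. Its column medians were 0.111, 0.114 and 0.112 for corn oil and 0.113, 0.114 and 0.111 for ADBAQ. How the authors chose the constant is not given in the sources used here.

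From these values, 1319 control spots and 73 probes flagged as outliers on any array were left out. Signals were taken as log2 minus the 75th percentile of each array. Probes were tested when well above background on all 3 arrays of at least 1 group, which kept 42256 of 61584. Saturated spots were kept, and 7 tested probes were saturated on some array. The files hold no gene names, so accessions without versions were matched to a table of RefSeq genes (assembly GRCr8), used for symbols only. Of 61657 probes, 27460 (44.5%) were matched to 1 gene, 0 to several and 34197 to none, giving 15284 genes, and unmatched probes entered the probe count alone. Each gene was represented by its probe with the highest mean over the 6 arrays, and 12007 genes were tested.

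Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no covariates), with Benjamini-Hochberg adjustment at 0.05 and a fold limit of 2 (1 on the log2 scale). The R package data.table (version 1.17.8) read the files, and figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15. The labels describe the replicates as separate animals. A test by permutation of 3 against 3 cannot reach 0.05, so limma's p-values rest on its model. Where a tested probe was not well above background on every array of a group, the difference of a named gene is given as a bound: the mean of the bright group against the mean, per array of the dim group, of the higher of the lowest signal among probes well above background and the probe's own signal. A gene was called not above background when this held for all of its probes. The bounds apply to the main scaling.

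Before the data were examined, 26 gene lists were written from general knowledge of the kidney and of responses to foreign compounds. They cover the AhR, CAR and PXR, Nrf2, p53 and PPAR-alpha, conjugating enzymes, DNA repair, the cell cycle, injury, tubule segments, glomerulus, endothelium, fibroblasts, leukocytes, red cells, the adrenal gland, metabolism, stress and lysosomes. Lists of at least 5 measured genes were tested with camera (preset correlation 0.01), with adjustment over the 26 lists. Camera with an estimated correlation and fry were alternatives, and fry does not compare a list with other genes. None of the 7 camera calls held with an estimated correlation. For red cells and UDP-glucuronosyltransferases the estimate was -0.015 and -0.0074, below the preset 0.01. A larger correlation between genes therefore does not account for the loss of those calls. The rule for named genes was also set beforehand: the 12 largest rises and 12 largest falls among changed genes measured on all 6 arrays, with no overlap between groups and a symbol; the 5 largest bounds in each direction; per list, up to 4 changed members or else the 2 with the smallest p; and a fixed set of genes of foreign-compound response, damage, proliferation and nephron segments. Results for 3 genes that this rule named are not reported here, and no others took their place.

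Scripts were tested on simulated data with the measured means and spreads of the 12007 genes of this comparison and 200 changed genes per run. Over 10 runs, 45.4% of changes of 0.5 on the log2 scale, 78.8% of changes of 1, 91.2% of changes of 2 and 97.6% of changes of 3 were recovered, with 9.8 false calls per run on average. A shift of 0.5 in the Nrf2 list was called in 10 of 10 runs, with 1 call over all runs among lists without a planted shift, leaving out the overlapping glutathione transferase list. These simulated genes vary independently, while the correlation estimated in the data was as high as 0.51, for the cell cycle list. The 1 list call therefore does not measure how often camera calls lists falsely in the data. In the data 35 genes were called, fewer than the 200 changes planted, so the adjusted threshold was stricter there. The recovered shares, above all for changes of 0.5, are therefore likely too high for the data, where the smallest change called was 0.68. Alternatives were median scaling, quantile normalization, no scaling, normexp with an offset of 50, other detection filters, the mean of a gene's probes, an intensity trend with robust variances, the replicate number as a block, the authors' table, and leaving out each array. The scripts' normexp used the median signal, since the files used here hold no mean signal. The slide was not fitted, since each group lay on its own slide.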

Results

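The series asked how gene expression in the renal cortex, the outer part of the kidney, differed between rats given 1-amino-2,4-dibromoanthraquinone and rats given the vehicle. The compound, called ADBAQ here, is a brominated anthraquinone used in dye manufacture. Male Sprague-Dawley rats, 5 weeks old when bought, received ADBAQ at 1000 mg/kg/day (3 rats) or corn oil (3 rats) for 4 weeks. RNA from each rat was read on its own 1-colour Agilent rat array. The 75th percentile of the signal lay between 1126 and 1177 on the corn oil arrays and between 1279 and 1307 on the ADBAQ arrays, and 69.0% to 72.3% of probes were well above background. The number of arrays, 3 per group, limits the precision. Across genes, which are not independent replicates, log2 signals correlated at 0.991 to 0.992 within the corn oil group, at 0.994 within the ADBAQ group and at 0.988 to 0.991 between groups. The first principal component held 35.7% of the variance, and the corn oil and ADBAQ arrays lay on opposite sides of it.

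After ADBAQ, the genes that rose included the cytochrome P450 Cyp1a1, the glutathione transferases Gstm1, Gstp1 and Gsta3, the epoxide hydrolase Ephx1, the efflux transporter Abcc4, and the red cell genes Hbb, Alas2 and Hemgn. The genes that fell included the metallothioneins Mt1 and Mt2A, which bind zinc and copper. In limma's moderated test with Benjamini-Hochberg adjustment over 12007 genes, 27 genes were higher and 8 were lower, and 24 and 3 of these differed by 2-fold or more in fitted values. With bounds in place of values for probes near background these were 24 and 2, since the bound for B3gat2 lay under 2-fold. The changed genes were 0.291% of those tested. The smallest change that passed was 0.68 on the log2 scale and the median was 1.20, against a median standard error of 0.094 over all genes. A further measure of separation was broader: in 3312 genes (27.6%) the 3 ADBAQ arrays did not overlap the 3 corn oil arrays, where chance gives 10%, and 2333 genes had an unadjusted p under 0.05. Among probes, named or not, 105 changed, against 1 to 79 when 1 array was left out. All corn oil arrays shared 1 slide and scan and all ADBAQ arrays another, so slide, scan and treatment cannot be told apart. The count of higher genes was 11 without corn oil replicate 1, 16 without corn oil replicate 2, 14 without corn oil replicate 3 and 12 without ADBAQ replicate 2, and the counts of higher and lower genes were 72 and 84 with an intensity trend and robust variances and 67 and 78 with normexp background correction. They were 1027 and 54 without scaling, and limma called 0 and 0 with the replicate number as a block, where 2266 genes had an unadjusted p under 0.05.

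**Figure D1:**
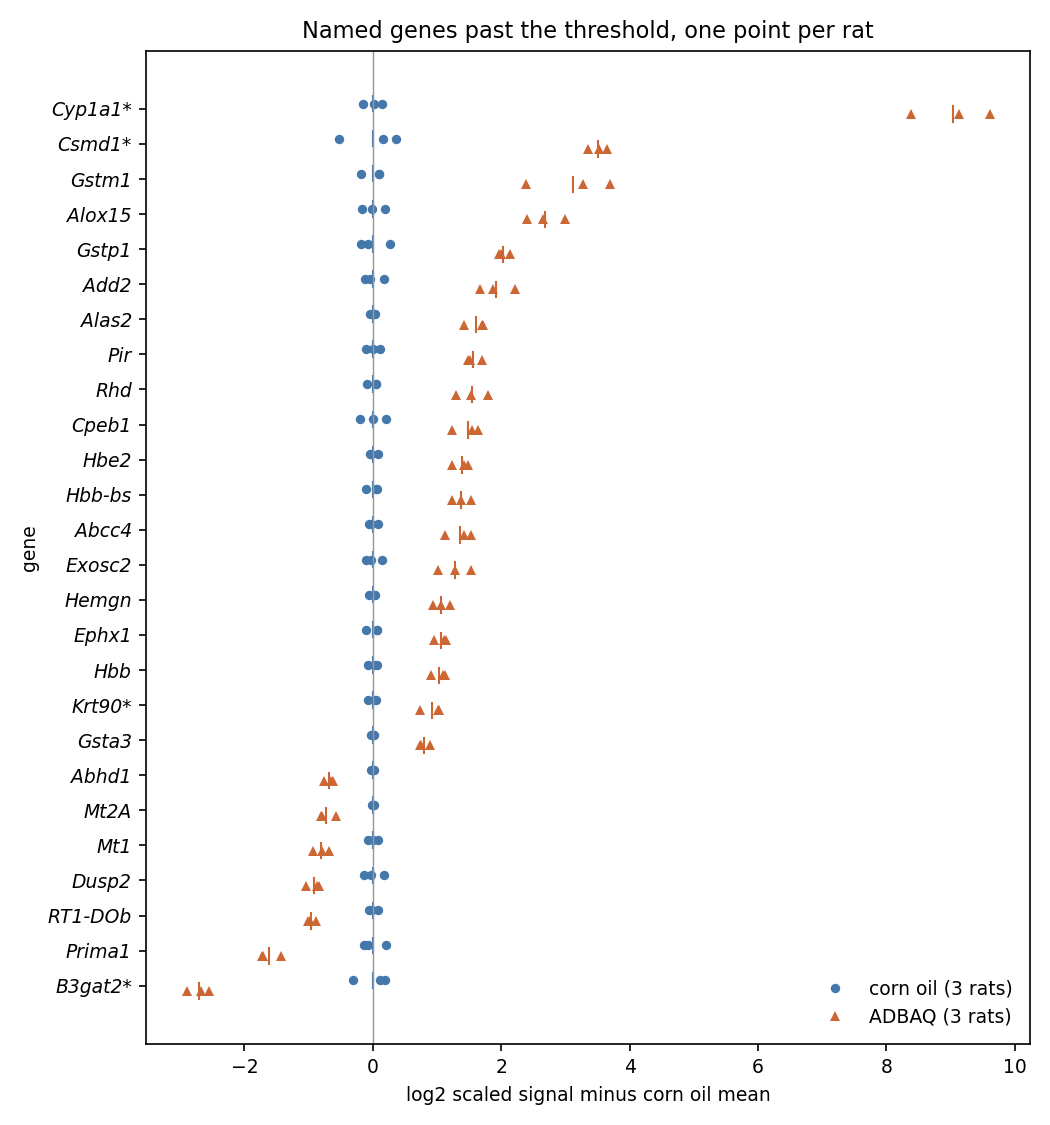
Log2 scaled signal minus the corn oil mean (horizontal axis) for the genes named under the rule that passed the threshold (vertical axis). Circles are corn oil rats, triangles are ADBAQ rats, and bars are group means; an asterisk marks a gene whose plotted probe was not well above background on any array of 1 group. Gstm1 differed by 3.12, Alox15 by 2.68 and Prima1 by -1.62, with no overlap between groups.

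Cyp1a1, the classical target of the aryl hydrocarbon receptor (AhR), had the largest difference of the genes tested. It was well above background on 3 ADBAQ arrays and on 0 corn oil arrays, so its rise is a bound: at least 129.6-fold (adjusted p = 0.0016). Of 9 measured AhR targets, Cyp1a1 passed over all genes tested. Adjusted over the list alone, 3 were higher and 1 was lower. Besides Cyp1a1, those higher were Cyp1a2 (at least 4.28-fold, adjusted p = 0.065 over all genes, not well above background in corn oil) and Nqo1, a quinone reductase (2.18 ± 0.55 SE on the log2 scale, n = 3 per group, adjusted p = 0.14). The lower one was Ahrr, a repressor of the receptor (-1.55 ± 0.40 SE, adjusted p = 0.14). Cyp1a1 and Nqo1 were in the fixed set of named genes, while Cyp1a2 and Ahrr were chosen after their values were seen. The median of the list was 0.16, also with Cyp1a1 and Cyp1a2 at their bounds. The list as a set did not pass limma's camera (adjusted p = 0.15, and 0.83 with an estimated correlation), while fry gave an adjusted p of 0.014. The camera value was 0.011 without ADBAQ replicate 2 and 0.010 with the mean of each gene's probes.

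Targets of Nrf2, the regulator of antioxidant and conjugation enzymes, were higher as a set by camera (adjusted p = 5.5e-11), and this was lost with an estimated correlation (adjusted p = 0.17). Of 29 measured members, 5 rose over all genes tested and 0 fell, and 22 of the other 24 had positive values. Of the 5 that rose, the 4 with the largest change were Gstm1 (3.12 ± 0.33 SE, 8.70-fold, adjusted p = 0.038), Gstp1 (2.03 ± 0.13, 4.07-fold, adjusted p = 0.0076), Abcc4 (1.36 ± 0.12, adjusted p = 0.016) and Ephx1 (1.07 ± 0.084, adjusted p = 0.012). Adjusted over the list alone, 15 were higher.

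Glutathione transferases, which conjugate electrophiles to glutathione, share 4 genes with the Nrf2 list. Of 18 measured, Gstm1, Gstp1 and Gsta3 (0.79 ± 0.063 SE, adjusted p = 0.012) rose. Adjusted over the list alone, 8 were higher and 1 was lower, and the last, Mgst3, was chosen after its value was seen (-0.36 ± 0.056 SE). The camera test gave an adjusted p of 5.2e-04, and an adjusted p of 0.40 with an estimated correlation. Of 9 UDP-glucuronosyltransferases, which attach glucuronic acid, 0 passed limma's test over all genes, 6 had an unadjusted p under 0.05 and 5 were higher when adjusted over the list alone. Ugt2b15 had a difference of 1.80 ± 0.36 SE (adjusted p = 0.11) and Ugt1a9 one of 0.75 ± 0.15 SE (adjusted p = 0.10). The list median was 0.75, and camera gave an adjusted p of 8.0e-04, or an adjusted p of 0.17 with an estimated correlation and 0.084 without scaling between arrays. Inducible cytochromes and transporters under the receptors CAR and PXR did not pass as a set (adjusted p = 0.58), with 0 of 9 members past limma's threshold and 4 at an unadjusted p under 0.05. Within it, Abcc2 had a value of 0.94 ± 0.23 SE and Abcc3 one of 0.27 ± 0.088 SE. Their adjusted p values were 0.14 and 0.19.

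**Figure D2:**
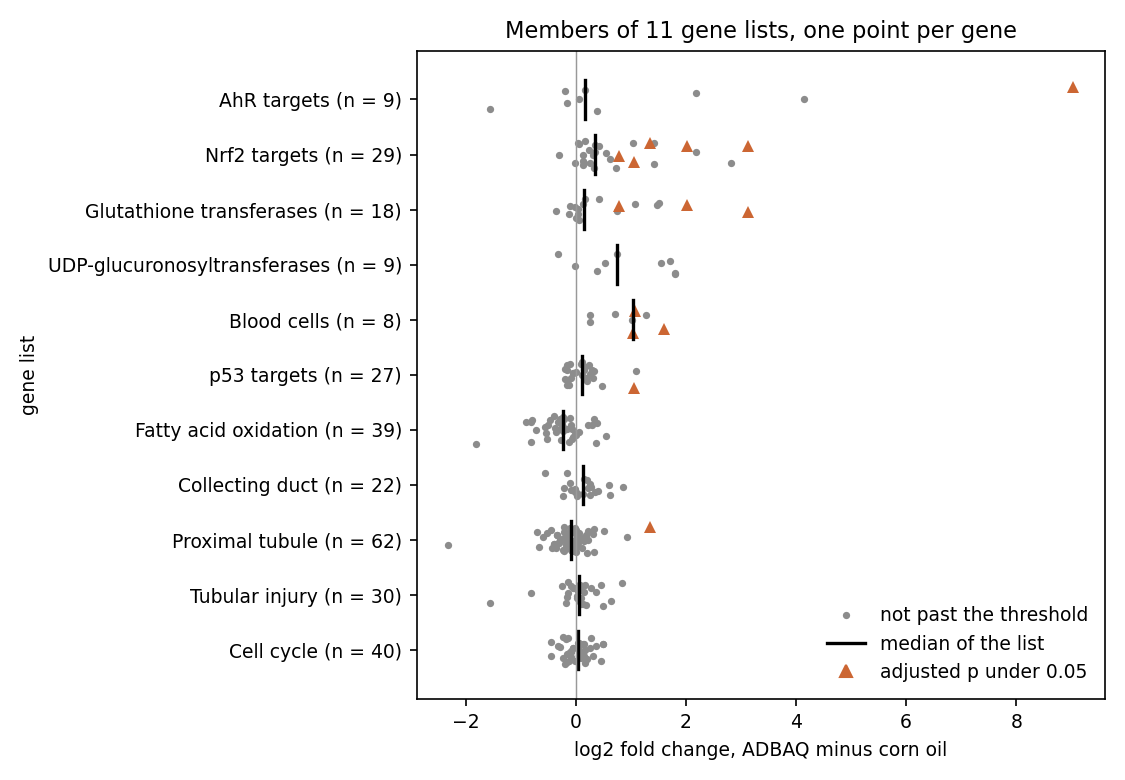
Log2 fold change of ADBAQ minus corn oil (horizontal axis) for the measured members of selected gene lists (vertical axis), with 1 point per gene. Triangles passed an adjusted p of 0.05 over all genes tested, grey points did not, and black bars are list medians, which were 1.03 for blood cells, 0.35 for Nrf2 targets and -0.24 for fatty acid oxidation.

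Red cell transcripts were also higher as a set by camera (adjusted p = 3.1e-09), and this was lost with an estimated correlation (adjusted p = 0.073). The correlation estimated was -0.015, below the preset 0.01. Of 8 measured members, 3 rose over all genes tested: Alas2, the first enzyme of heme synthesis in red cell precursors (1.61 ± 0.092 SE, 3.06-fold, adjusted p = 0.0065), Hemgn (1.07 ± 0.084, adjusted p = 0.012) and the beta globin Hbb (1.04 ± 0.080, adjusted p = 0.012). The other 5 had positive values, and 7 were higher when adjusted over the list alone. Among genes outside this list, Hbe2 (1.38 ± 0.085 SE) and Hbb-bs (1.38 ± 0.099) of the beta globin family, the blood group gene Rhd (1.54 ± 0.13) and Add2, a part of the red cell membrane skeleton (1.92 ± 0.16), rose, with adjusted p values of 0.0070, 0.0091, 0.016 and 0.013. Globin genes are near-identical copies, so their probes cannot be assigned to 1 copy with certainty. Leukocyte markers did not pass as a set (adjusted p = 0.33): of 34, 0 passed limma's threshold over all genes and 4 had an unadjusted p under 0.05. Cd52, a lymphocyte surface protein, had a value of 1.40 ± 0.20 SE (adjusted p = 0.064), and the chemokine Ccl2 one of 0.96 ± 0.25 (adjusted p = 0.14).

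Fatty acid oxidation genes, including targets of PPAR-alpha, were lower as a set by camera (adjusted p = 1.3e-04), and this was lost with an estimated correlation (adjusted p = 0.84) and by fry (0.28). Of 39 measured, 0 passed limma's test over all genes, 19 had an unadjusted p under 0.05, and adjusted over the list alone 14 were lower and 1 was higher. The last, Ppargc1a, was chosen after its value was seen (0.22 ± 0.059 SE). Pex11a, a peroxisomal membrane protein, had a value of -0.80 ± 0.10 SE (adjusted p = 0.055) and Hadh, an enzyme of mitochondrial beta-oxidation, one of -0.46 ± 0.066 (adjusted p = 0.064). The list median was -0.24.

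Targets of p53, induced after DNA damage, passed camera with a small shift (median 0.11, adjusted p = 0.029), and this was lost with an estimated correlation (adjusted p = 0.67) and by fry (0.083). Of 27 measured, 1 rose over all genes, Ephx1, which is also in the Nrf2 list and acts in detoxification. Adjusted over the list alone, 6 were higher. Mdm2, the p53 ubiquitin ligase, had a value of 0.34 ± 0.064 SE (adjusted p = 0.10), Ccng1 one of 0.30 ± 0.083 (adjusted p = 0.16), and Cdkn1a, the p21 cell cycle inhibitor, one of 0.0065 ± 0.097 (adjusted p = 0.98). Camera's adjusted p for the list was 0.20 without corn oil replicate 1, 0.085 without corn oil replicate 3 and 0.062 without ADBAQ replicate 2. It was 0.093 without scaling, 0.072 without the detection filter and 0.060 with the replicate block. The lists for DNA repair (adjusted p = 0.72, 28 genes) and cell cycle (adjusted p = 0.62, 40 genes) did not pass. Neither had a member past limma's threshold, and 4 and 3 members had an unadjusted p under 0.05. Xpa and H2ax led the first list with 0.24 ± 0.062 SE and -0.30 ± 0.071 (adjusted p = 0.14 and 0.13). In the other list, Rrm1 had 0.36 ± 0.088 SE, Pcna 0.15 ± 0.051 and Cdk1 -0.049 ± 0.21, with adjusted p values of 0.14, 0.21 and 0.91. Mki67, Top2a and Cyp1b1 were not among the genes tested.

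Transcripts known to rise in damaged tubules did not pass as a set (adjusted p = 0.33). Of 30 measured, 0 passed limma's threshold and 1, Spp1 (osteopontin), had an unadjusted p under 0.05, with a value of 0.84 ± 0.18 SE (adjusted p = 0.12). Values for Havcr1 (KIM-1), Clu, Lcn2 and Cd44 were 0.64 ± 0.63 SE, 0.50 ± 0.30, 0.37 ± 0.20 and 0.29 ± 0.14, with adjusted p values of 0.61, 0.41, 0.35 and 0.32. When 1 array was left out these values ran from 0.0092 to 1.29, 0.16 to 0.75, 0.17 to 0.52 and 0.14 to 0.36. Proximal tubule genes did not pass (adjusted p = 0.44). Of 62, Abcc4 rose and none of the rest passed over all genes, with 18 members at an unadjusted p under 0.05. Adjusted over the list alone, 3 were higher and 2 lower. The anion transporter Slc22a6 (-0.16 ± 0.065 SE), the phosphate transporter Slc34a1 (-0.053 ± 0.053) and the receptor Lrp2 (-0.18 ± 0.073) had adjusted p values of 0.25, 0.62 and 0.25.

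Collecting duct markers passed camera (median 0.14, adjusted p = 0.029) and lost this with an estimated correlation (adjusted p = 0.84) and by fry (0.51). Of 22, 0 passed limma's threshold over all genes, 6 had an unadjusted p under 0.05 and 2 were higher when adjusted over the list alone: the anion exchanger Slc4a1 (0.62 ± 0.13 SE, adjusted p = 0.12) and the ammonia transporter Rhcg (0.41 ± 0.090, adjusted p = 0.12). Slc4a1 is also the band 3 protein of red cells. The water channel Aqp2 had a value of -0.10 ± 0.16 SE (adjusted p = 0.76). Camera's adjusted p was 0.30 without corn oil replicate 1, 0.074 without corn oil replicate 3, 0.17 without ADBAQ replicate 1 and 0.062 without ADBAQ replicate 2. It was 0.36 without scaling, 0.079 without the detection filter and 0.055 with the replicate block.

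Markers of other kidney compartments and cell types did not pass camera as sets. For thick limb and distal tubule genes the adjusted p was 0.49, with Cldn10 at -0.38 ± 0.11 SE, Atp2b1 at -0.24 ± 0.072, Umod at -0.17 ± 0.21 and Egf at 0.27 ± 0.16. For medulla markers it was 0.53, with the water channel Aqp4 at 0.85 ± 0.23 SE and Krt7 at -0.41 ± 0.066. For glomerulus markers it was 0.53, with Nes at 0.23 ± 0.078 SE and Tcf21 at 0.30 ± 0.11. For endothelium it was 0.58, with Ehd3 at -0.47 ± 0.10 SE and Sox17 at 0.30 ± 0.089. For fibroblasts and matrix it was 0.33, with the collagen Col1a1 at -0.62 ± 0.16 SE and the proteoglycan Bgn at -0.26 ± 0.095. For adrenal gland genes it was 0.58, with Th at 0.27 ± 0.067 SE and Cyp11a1, well above background on 1 of 3 ADBAQ arrays, at a bound of -0.59 with overlap between groups. The adjusted p values of these single genes lay above 0.05.

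Metabolic and stress lists outside fatty acid oxidation did not pass either. The adjusted p was 0.44 for cholesterol synthesis, where Hsd17b7 had a value of -0.43 ± 0.085 SE and Mvd one of -0.34 ± 0.11. It was 0.92 for oxidative phosphorylation, with Cs, the citrate synthase, at 0.20 ± 0.055 SE. It was 0.56 for the unfolded protein and amino acid stress genes, with Ddit4 at -1.06 ± 0.20 SE and Psat1 at -0.28 ± 0.067. It was 0.56 for heat shock, with Hspa4l at 0.24 ± 0.11 SE and Hspd1 at 0.12 ± 0.059. It was 0.35 for the renin angiotensin and kallikrein genes, with the angiotensin converting enzyme Ace at -0.95 ± 0.21 SE. This list passed in the lower direction without scaling (adjusted p = 0.038, with 0.038 to 0.84 over the alternatives). It was 0.80 for lysosome genes, with the autophagy receptor Sqstm1 at 0.35 ± 0.091 SE and the lipase Lipa at 0.27 ± 0.077. None of these single genes passed limma's threshold over all genes. Median and mean differed in sign for the CAR and PXR and the adrenal gland lists, and the median lay below 0 while camera pointed up for endothelium, oxidative phosphorylation and lysosome.

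Outside the lists, Csmd1, which encodes a membrane protein with complement control domains, was not well above background in corn oil and was at least 9.92-fold higher after ADBAQ (adjusted p = 0.0087). The lipoxygenase Alox15 rose by 2.68 ± 0.17 SE (6.41-fold, adjusted p = 0.0076). Pir, an iron-binding nuclear protein, rose by 1.56 ± 0.089 SE, Cpeb1, which binds messenger RNA, by 1.48 ± 0.15, and Exosc2, a part of the RNA exosome, by 1.27 ± 0.15. Their adjusted p values were 0.0065, 0.028 and 0.049. The keratin Krt90, not well above background in corn oil, was at least 1.81-fold higher (adjusted p = 0.038).

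Among genes that fell, B3gat2, a glucuronyltransferase of glycan synthesis, was not well above background after ADBAQ and was at least 1.45-fold lower (adjusted p = 0.0065). Prima1, the membrane anchor of acetylcholinesterase, fell by 1.62 ± 0.13 SE (adjusted p = 0.012). RT1-DOb, a class II histocompatibility gene, fell by 0.96 ± 0.067 (adjusted p = 0.0088) and the phosphatase Dusp2 by 0.92 ± 0.10 (adjusted p = 0.043). Mt1 fell by 0.80 ± 0.086, Mt2A by 0.73 ± 0.078 and Abhd1 by 0.68 ± 0.061, with adjusted p values of 0.038, 0.038 and 0.018. A further gene, Zbtb16, a transcription factor chosen after its values were seen, was at least 2.67-fold lower (adjusted p = 0.0065), with its tested probe well above background on 0 of 3 ADBAQ arrays. The other 8 genes past the threshold outside the naming rule rose by 0.89 to 1.20. Of the named genes past the threshold, 9 (Cyp1a1, Csmd1, Alox15, Gstp1, Alas2, Pir, Hbe2, B3gat2 and RT1-DOb) stayed past it whichever 1 array was left out, and the other 17 lost it in 2 to 6 of the 6 cases. The call was also lost for Cpeb1, Dusp2, Exosc2, Gstm1, Krt90, Mt1 and Mt2A without the detection filter, for B3gat2 and Krt90 with normexp, for Add2 and Exosc2 with the mean of probes, for Krt90 with an intensity trend and for Exosc2 among genes above background on all 6 arrays. None of the changed genes had another probe that changed the opposite way, among the 21 with more than 1 probe. For Add2, Exosc2, Prima1 and Hemgn the 1 other tested probe did not pass. For the remaining named genes with more than 1 probe, each other probe passed in the same direction.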

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

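The spike-in comparisons below were chosen after their results had been seen, and the splits were planned. Among probes with no gene name, which enter no gene comparison, 14 were well above background on 3 ADBAQ arrays and on 0 corn oil arrays, a signal in data outside the gene comparison. In the opposite direction there were 74 such probes. The lowest signal among probes well above background was 14.6 to 19.4 on corn oil arrays and 18.8 to 23.6 on ADBAQ arrays, so the limit itself varied between arrays, with overlap between the groups.

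The pattern with the widest reach is the set of 35 genes changed after ADBAQ, because treatment followed slide and scan. A slide or scan difference that depends on brightness would also move the spike-in RNAs added to each sample apart from each other. In scaled signals, the 8 spike-ins in range differed by a median of -0.22 on the log2 scale between slides. The percentile subtracted in scaling was higher on the ADBAQ arrays, and scaling moved the median of all genes to -0.011 from 0.15. Much of the -0.22 therefore comes from the scaling, so it does not measure a slide difference alone. After this common shift was removed the largest difference was 0.0618, against 0.68 for the smallest change called in a gene. This argues against such a difference as the source of the 27 called genes whose group means lay within the spike-ins' range (-4.29 to 8.80). The other 8, most of them dim, lay outside it. There, spike-ins below background differed by up to 0.41. The smallest change among the 8, 0.80, was that of Mt1. Its corn oil mean (8.87) lay above the brightest spike-in, so spike-ins below background do not bear on it. A difference of 0.41 would not account for the bounds of Cyp1a1 (7.02) and Csmd1 (3.31) on the log2 scale. The bound of B3gat2 (-0.54) lay closer to it. For the genes other than Cyp1a1 and Csmd1 the explanation stays open. A difference acting on all spots alike was not tested, since the scaling and then the removal of the common shift take it out. Batches of RNA extraction, handling of the rats and dates of sampling are not given in the sources used here and were not tested.

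The 6 arrays can be split into 3 and 3 in 10 ways, the real one included, so no share under 0.05 can be reached. As many changed genes as the real 35 came from 1 of the 10 splits, the real one, and the highest of the others was 0. For genes changed by 2-fold or more it was also 1 of 10, with 27 against 0, and for probes 1 of 10, with 105 against 1. Gene lists behaved otherwise: 6 of the 10 splits moved at least as many lists as the real 7, and the highest of the others moved 10.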

How the results depend on the processing

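Depth was limited by signal over background on 3 arrays per group. The normexp alternative was chosen after the data were examined, because the planned one needs a signal the files used here lack, and a fit with slide as a block was not run, since each group lay on its own slide. Median scaling, quantile normalization and the authors' table left the counts of genes, probes and lists within 1.5 times, and shared 27, 27 and 27 of the 27 higher genes. The authors' table holds the same signals over nearly the same constant, so its result was fixed in advance and is no separate check. In numbers of named genes, without any scaling 22 gained the call and 4 changed sign. The 35 changed genes had the same sign in each of the 16 alternatives that gave them a value, and passed the threshold in 6 to 15 of them. Sizes given as bounds did not hold in each alternative. With no array left out, fitted log2 values came as low as 5.07 for Cyp1a1, 1.48 for Csmd1 and 0.14 for Krt90. For B3gat2 they came as high as -0.26. Each of these lay closer to no change than its bound.

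Without scaling, 1027 genes were higher and 54 lower (70 and 13 by 2-fold or more), 2743 probes changed, and 3 lists were higher and 2 lower, fatty acid oxidation and the renin angiotensin and kallikrein genes. That moved the median of all genes to 0.15 from -0.011 and the share of higher genes among those changed to 95.0% from 77.1%. The 1027 included the 27. With normexp, 67 genes were higher and 78 lower (8 lower by 2-fold or more) and 427 probes changed, with 25 of the 27 and 7 of the 8 among them. With an intensity trend and robust variances the counts were 72 higher, 84 lower (13 lower by 2-fold or more) and 469 probes, with 26 of the 27 and 8 of the 8 among them. Without the detection filter 4 genes were lower and 35 probes changed, with more genes tested (15276), and among genes above background on all 6 arrays 1 was lower by 2-fold or more. Over the 12 alternatives that left no array out, adjusted p values ran from 1.1e-11 to 0.17 for Nrf2 targets, 3.2e-04 to 0.40 for glutathione transferases, 7.6e-05 to 0.17 for UDP-glucuronosyltransferases, 0.0099 to 0.67 for p53 targets, 0.010 to 0.84 for collecting duct, 1.2e-09 to 0.073 for red cells, 5.5e-09 to 0.84 for fatty acid oxidation, 0.038 to 0.84 for renin angiotensin and kallikrein genes and 0.010 to 0.95 for AhR targets. Camera with an estimated correlation called 0 lists higher and 0 lower, and fry called 0 lower. Apart from the changes in what was tested that these settings make, the cause was not tested.

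Replicate numbers shared by the groups showed no clear pairing of the rats. The deviations of same-numbered arrays correlated at 0.0094, 0.16 and 0.035, with 1 pair over 0.1. Corn oil replicates 1 and 2 correlated best with their own number, replicate 1 by little (0.0094 against 0.0076). Corn oil replicate 3 did so with ADBAQ replicate 1 (0.13). Deviations from the mean of 3 arrays cannot exclude pairing. With the replicate block, which leaves fewer degrees of freedom, limma called 0 genes higher and 0 lower (0 and 0 by 2-fold or more) and 0 probes, with 2266 genes at an unadjusted p under 0.05. It called 4 lists higher and 1 lower, without p53 targets (adjusted p = 0.060) and collecting duct (0.055).

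Leaving out 1 array at a time, with fewer samples, gave 11 to 25 genes higher and 3 to 10 lower, 10 to 21 higher and 2 to 8 lower by 2-fold or more, 1 to 79 probes, 4 to 7 lists higher and 1 list lower throughout. Without corn oil replicate 1, 11 genes were higher, 3 lower and 4 probes changed. Without corn oil replicate 2 these were 16, 6 and 9, without corn oil replicate 3 they were 14, 8 and 16, without ADBAQ replicate 1 they were 24, 5 and 25, and without ADBAQ replicate 2 they were 12, 3 and 1.

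Named genes that changed sign had small values and did not pass in the main comparison. Cdkn1a was at -0.0027 with median scaling and -0.037 with the mean of probes. Without scaling Aqp2 was at 0.063, Cdk1 at 0.11, Slc22a6 at 8.6e-04 and Slc34a1 at 0.11. Over left-out arrays the values ran from -0.23 to 0.074 for Aqp2, -0.24 to 0.093 for Cdk1, -0.048 to 0.10 for Cdkn1a and -0.33 to 0.0056 for Umod. The cause was not tested.

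Lists whose direction turned did not pass in either case, by adjusted p. These were oxidative phosphorylation with median scaling (0.98), without the filter (0.85) and by fry (0.95), and CAR and PXR targets (0.93), cell cycle (0.56), medulla (0.97), adrenal gland (0.93) and unfolded protein and amino acid stress (0.97) without scaling. With normexp they were medulla (0.88) and lysosome (0.76), and without the filter DNA repair (0.94) and lysosome (0.93).
Over left-out arrays some also turned, and adjusted p values ran from 0.10 to 0.92 for cell cycle, 0.042 to 0.89 for glomerulus (past the threshold without ADBAQ replicate 3, in the direction of the main comparison), 0.68 to 0.99 for oxidative phosphorylation, 0.082 to 0.97 for the unfolded protein and amino acid stress list, 0.21 to 0.99 for heat shock and 0.28 to 0.99 for lysosome. The cause was not tested.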

Other observations

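The tests below and their bounds were written before their results were seen, on genes listed beforehand, while the 2 patterns themselves were found in the data. The rules that decide 4 of the tests (whole blood, young red cells, glucocorticoid targets and time of day) were revised after their values were seen, those for young red cells and glucocorticoid targets 2 times. Under the bounds as first written, the glucocorticoid test would have counted for its explanation and the other 3 against theirs. The values did not change, and the reason for each revision is given with its test. Platelet and granulocyte transcripts, a list outside the report, shifted upward: of 19 measured genes, 15 had positive values, and the mean over the list was 0.26 ± 0.039 (SE over arrays) higher after ADBAQ, with no overlap between groups, and 0.43 higher without scaling. The platelet genes Treml1 and Pf4 had values of 0.58 ± 0.075 SE and 0.64 ± 0.35, and the granulocyte genes Camp and Csf3r 0.55 ± 0.11 and 0.58 ± 0.16. None passed limma's threshold over all genes, and 4 had an unadjusted p under 0.05. Of the clock genes that peak with Bmal1, 5 of 5 had positive values (mean 0.27 ± 0.14 SE), and of those that peak with Dbp, 4 of 6 had negative values (mean -0.22 ± 0.22 SE). Without scaling these means were 0.43 and -0.061. None of these passed either, with 2 and 1 at an unadjusted p under 0.05. Genes shown here were chosen after their values were seen.

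Red cell transcripts, led by Alas2, Hbb and Hemgn, were higher after ADBAQ. One candidate explanation is more whole blood left in the tissue, which would raise platelet and granulocyte transcripts too. Their median change was 0.35, below the bound of 0.52 that the test took from the rise of Hbb. The members' own spread (SD 0.29) exceeds that gap, so the first bound, 2 standard errors of the list's mean, was taken to be too strict and this explanation was left open. That SD describes how much the genes differ from each other, not the error of the list's change between groups. The other candidate is more young red cells in blood or tissue. Red cell genes outside the first list moved by 0.13 ± 0.034 SE on average, less than the platelet and granulocyte genes (difference -0.14 ± 0.033 SE), which meets the bound first written against this explanation. The 9 of 15 that lay under the 75th percentile in corn oil rats also averaged 0.13. They too were well above background, so this split cannot settle what part the kidney's own expression plays. Without scaling the mean of the 15 was 0.29. The difference lies within the spread of the members (SD 0.23 and 0.29), but that spread is between genes and is not the error of the difference. However, by design the list leaves out the red cell genes of the first list, 3 of which passed. The test was therefore taken to exclude nothing, and the 2 explanations cannot be told apart.

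Zbtb16 (at least 2.67-fold), Per1 (-1.43), Sgk1 (-1.36), Ddit4 (-1.06), Mt1 (-0.80) and Mt2A (-0.73) were lower after ADBAQ. Per1, Sgk1 and Ddit4 did not pass limma's threshold (adjusted p = 0.070, 0.055 and 0.10). All 6 are known to respond to glucocorticoids, so a candidate explanation is less glucocorticoid signalling in the ADBAQ rats. Of 13 other glucocorticoid targets, 9 had negative values, and their mean was -0.21 ± 0.070 SE, below 0 as the test had set for this explanation. It lay within the members' own spread (SD 0.34), the measure used for the red cell tests, and so was taken to leave the explanation open. That SD describes how much the genes differ from each other and is not the error of their mean. Without scaling the mean was -0.049 ± 0.077 SE, with the median of all genes at 0.15, and would have met the bound set against it. Klf9 (-0.54 ± 0.11 SE), Tsc22d3 (-0.47 ± 0.095) and Fkbp5 (-0.74 ± 0.40) were among them. Sampling of the groups at different times of day may act on several of the same genes: Dbp-phase minus Bmal1-phase clock genes gave -0.49 ± 0.36 SE, within 2 standard errors of 0 but too wide to exclude a shift of the size seen in the pattern (at least 0.73), so the first bound was set aside and this stays open.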
